A study of Mus musculus with 6 samples.

How the data were processed

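RNA from 3T3-L1 cells, a mouse embryonic fibroblast line that can turn into fat cells in culture, was sequenced in 6 libraries. The titles and cell type labels gave 3 preadipocyte and 3 adipocyte libraries, each numbered 1 to 3. Per the labels, the medium description was the same for all 6 samples and holds the abbreviation DMI, which is not spelled out, so what each group received is not known from it. The source name reads Adipocyte for all 6 samples, preadipocytes included, so the groups rest on the titles and the cell type labels. Per the labels, the treatment was none, RNA was isolated with phenol-chloroform and libraries followed a standard Illumina protocol. The day of harvest, the selection of RNA and the strandedness of the libraries are not given in the sources used here. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

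The authors deposited 1 gene table per library. Per the file headers, the tables hold the length, effective length, expected count, TPM and FPKM of each gene, which is the layout of RSEM. Per the submitters' processing notes, RSEM, Bowtie, Bowtie2 and DESeq2 were used with the builds GRCm38 and mm10. The notes give neither a version nor the role of each tool. The deposited expected counts are estimates that share out reads matching several genes, and they are not scaled between libraries. The deposited TPM values are scaled within each library by the authors' quantification. The deposited effective length is another value per gene and library, the length over which a read could start, and it was used only in an alternative setting. FPKM was not used here. A gene whose reads also match a near-identical copy has an uncertain count, because the expected counts divide such reads by a model. Without a statement on strand, reads of overlapping and antisense genes cannot be told apart either.

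Each table listed 54752 genes. Gene identifiers without their version suffix were matched to GENCODE M21 on GRCm38 for symbols and positions, and 54723 matched. Where several identifiers carried 1 symbol, the symbol was kept for the most abundant of them, which left 102 identifiers named by symbol and identifier. Total expected counts ran from 22496486 to 26314076 per library. No pair of libraries was identical. The closest pair, preadipocyte libraries 2 and 3, had a chi-square of 2.99 per degree of freedom over 14400 genes, so every pair differed by more than counting noise and each library was kept as 1 replicate.

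Expected counts were rounded to whole numbers first. Genes with enough counts by the filterByExpr rule of edgeR 4.0.16 (R 4.3.3) were tested with its quasi-likelihood F-test after TMM normalization, with the group as the only term and Benjamini-Hochberg adjustment at 0.05. CPM values use the TMM-scaled library size, and errors are SDs over 3 libraries or standard errors of the fitted log2 fold change. TMM factors were 1.11 to 1.13 in preadipocyte and 0.88 to 0.90 in adipocyte libraries. A gene with 0 counts in a group is given a lower bound computed from a floor of 3 counts summed over the 3 libraries of that group, which equals 0.0383 CPM in preadipocytes and 0.0443 CPM in adipocytes. A gene with 1 to 3 counts in a group is given the ratio with an exact 95% Poisson interval for those counts. Bounds and intervals cover counting error only. Fitted fold changes of such genes depend on the prior count of the tool.

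Before the data were examined, 36 gene lists were fixed from textbook knowledge, 7 of them markers of other cell types. Of these, 33 had at least 3 tested members and were tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01. Member counts came from the edgeR fit, and counts adjusted over the list alone differed from them in 0 of the 36 lists. The genes to be named were fixed by a rule at the same time. They were Pparg, Cebpa, Fabp4, Adipoq, Plin1 and Dlk1, then the 5 largest rises and 5 largest falls among genes past the threshold with at least 10 CPM in the higher group and no overlap between groups. The rule added the 2 leading members of each main list with the largest opposing one, the leading member of each supporting list and the most abundant marker of each other cell type. Clone names and accession-like symbols were passed over. Other genes named below were chosen after their values were seen, to describe exceptions within lists or in the closing observations.

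The replicate numbers were checked for pairing. Deviations of log2(CPM + 1) from the group means correlated across genes at 0.66 for the libraries numbered 1, 0.30 for those numbered 2 and 0.26 for those numbered 3, and 4 of 6 libraries correlated best with the library of their own number. All 3 correlations exceeded the limit of 0.1 set for pairing, so a fit with the replicate number as a block was run beside the one without it. Unmatched numbers also correlated, at 0.45 for preadipocyte 2 with adipocyte 3 and 0.16 for preadipocyte 3 with adipocyte 2. Deviations within a group cancel out, so the shared deviation of the libraries numbered 1 raises all these values. The libraries numbered 2 and 3 therefore give no separate evidence of pairing. The labels do not say what the numbers share.

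Alternatives were RLE and upper-quartile factors, total counts, other filters, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), effective length as an offset, the replicate block, leaving out each library, leaving out 37 mitochondrially encoded genes or the 50 most abundant genes, and for the lists an estimated correlation, ranks and fry. On simulated counts with the preadipocyte means and with the dispersions and library sizes of this comparison (14000 genes tested), edgeR recovered 72 of 95 genes changed 2-fold and 43 of 96 changed 1.5-fold. It also called 12 unchanged genes, 9.4% of its calls, which is above the nominal level. With 3 of 32 simulated lists raised, camera found 3 and called 0 others, but simulated genes varied independently, so this does not test correlation between genes.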

Results

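The series compared 3T3-L1 preadipocytes with 3T3-L1 adipocytes by RNA sequencing, with 3 libraries per state. Total expected counts were 23353856 ± 994731 (SD, n = 3) in preadipocyte and 25282898 ± 1251458 (SD, n = 3) in adipocyte libraries. Collagen gene Col1a2 was the most abundant transcript in each preadipocyte library, at 1.42% to 1.56% of counts. The fatty acid desaturase gene Scd1 was the most abundant in each adipocyte library, at 3.15% to 3.70%. The 10 most abundant genes took 7.65% ± 0.14 (SD, n = 3) of counts in preadipocytes and 13.9% ± 0.62 (SD, n = 3) in adipocytes. Adipocyte library 2 stood apart in its share of ribosomal RNA, 0.731% against 0.0494% and 0.0706% in adipocyte libraries 1 and 3.

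The comparison asked which transcripts differ between the 2 states. In adipocytes, 19 of 20 genes of fatty acid and triglyceride synthesis and all 14 genes of fatty acid uptake and lipolysis (13 with total counts or limma on log2(TPM + 1)) were higher, and 24 of 28 cell cycle genes were lower. These lists passed camera with an estimated correlation between genes (adjusted p = 0.030 for each), but not when the replicate number was a block as well (adjusted p = 0.17 for each). An estimated correlation leaves camera few residual degrees of freedom, and fewer with the block. The outcome with the block therefore does not count against the lists, and the pass without it is weak support. With the preset correlation they passed with the block too. Up to 26 lists also passed with the preset correlation when the 6 libraries were regrouped, but each regrouping keeps part of the real difference. Pparg, the nuclear receptor that drives fat cell formation, rose from 37.9 ± 1.39 to 567.6 ± 7.97 CPM (SD, n = 3). The secreted hormone gene Adipoq went from 0.117 ± 0.080 to 4525 ± 821 CPM (SD, n = 3), and the preadipocyte marker Dlk1 fell from 3245 ± 531 to 140.6 ± 27.0 CPM (SD, n = 3).

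Of 14726 tested genes, 5252 were higher and 5575 lower in adipocytes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At least 2-fold differences were found for 2849 higher and 3211 lower genes. The groups did not overlap for 11261 genes, or 76.5%, where chance gives 10%. Among the called genes, 100 had 0 counts in all preadipocyte libraries and 32 had 0 counts in all adipocyte libraries. The balance of directions differed between settings. Higher genes were 48.5% of calls with TMM, 34.3% with total counts alone and 28.2% with limma on log2(TPM + 1), which changes the unit and the test together and gave 3266 higher and 8328 lower genes. Relative to TMM, the median gene shifted by -0.13 (log2) with upper-quartile factors, -0.33 with total counts and -0.48 with limma on log2(TPM + 1).

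**Figure D1:**
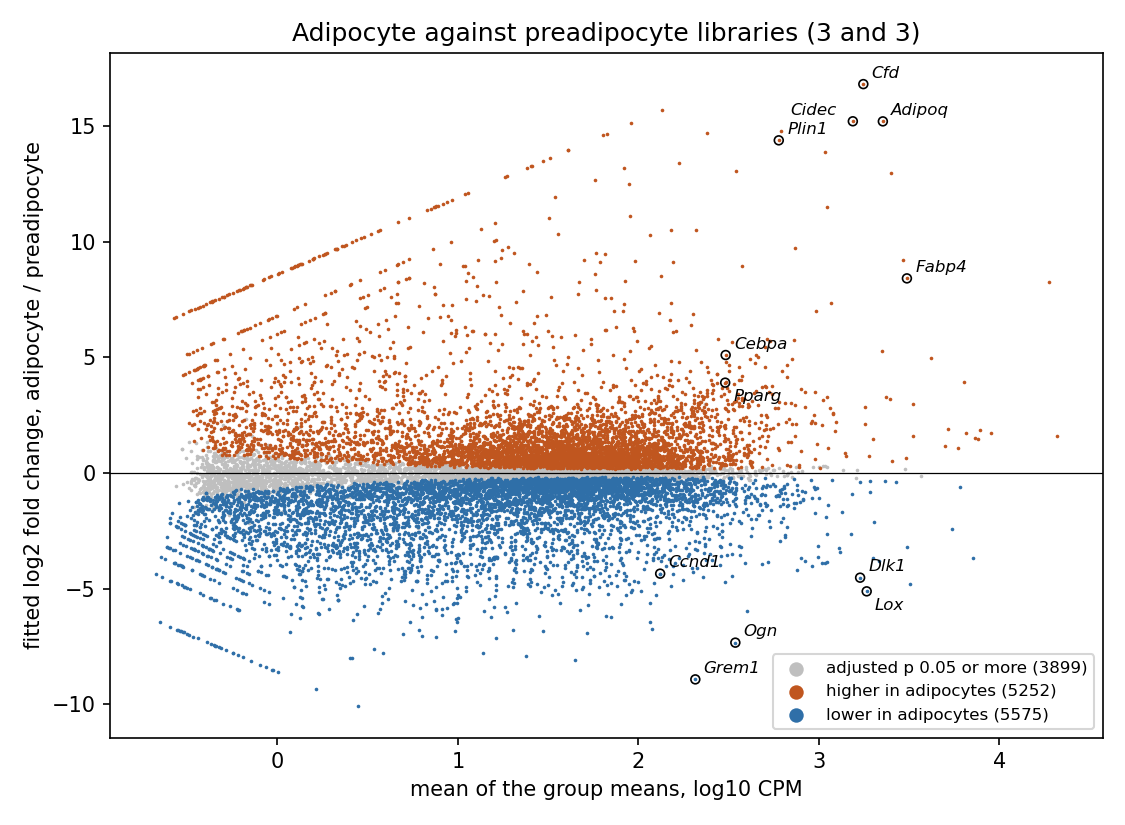
Fitted log2 fold change (adipocyte over preadipocyte) against mean abundance (log10 CPM) for the 14726 tested genes, each point 1 gene, with 5252 higher genes in orange, 5575 lower genes in blue and 3899 others in grey. Fitted values of genes with few counts in a group depend on the prior count, which draws the diagonal lines of points at the left.

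The 6 genes chosen in advance as references all changed. Pparg (ENSMUSG00000000440.12, chromosome 6, 115360951 to 115490399, GRCm38) rose by 3.90 on the log2 scale (SE 0.078, edgeR adjusted p = 2.16e-09). Cebpa (ENSMUSG00000034957.10, chromosome 7, 35119293 to 35121928), a transcription factor that acts with Pparg, rose by 5.10 (SE 0.13). The fatty acid carrier gene Fabp4 (ENSMUSG00000062515.3, chromosome 3, 10204088 to 10208576) rose from 17.99 ± 0.44 to 6134 ± 187 CPM (SD, n = 3). Adipoq (ENSMUSG00000022878.5, chromosome 16, 23146536 to 23158028) rose from 9 counts in the 3 preadipocyte libraries together to 306707 in the adipocyte libraries. Plin1 (ENSMUSG00000030546.14, chromosome 7, 79720218 to 79732903), which coats lipid droplets, rose from 4 to 81238 counts. Dlk1 (ENSMUSG00000040856.17, chromosome 12, 109452823 to 109463336) fell by 4.53 on the log2 scale (SE 0.18, edgeR adjusted p = 4.97e-08).

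**Figure D2:**
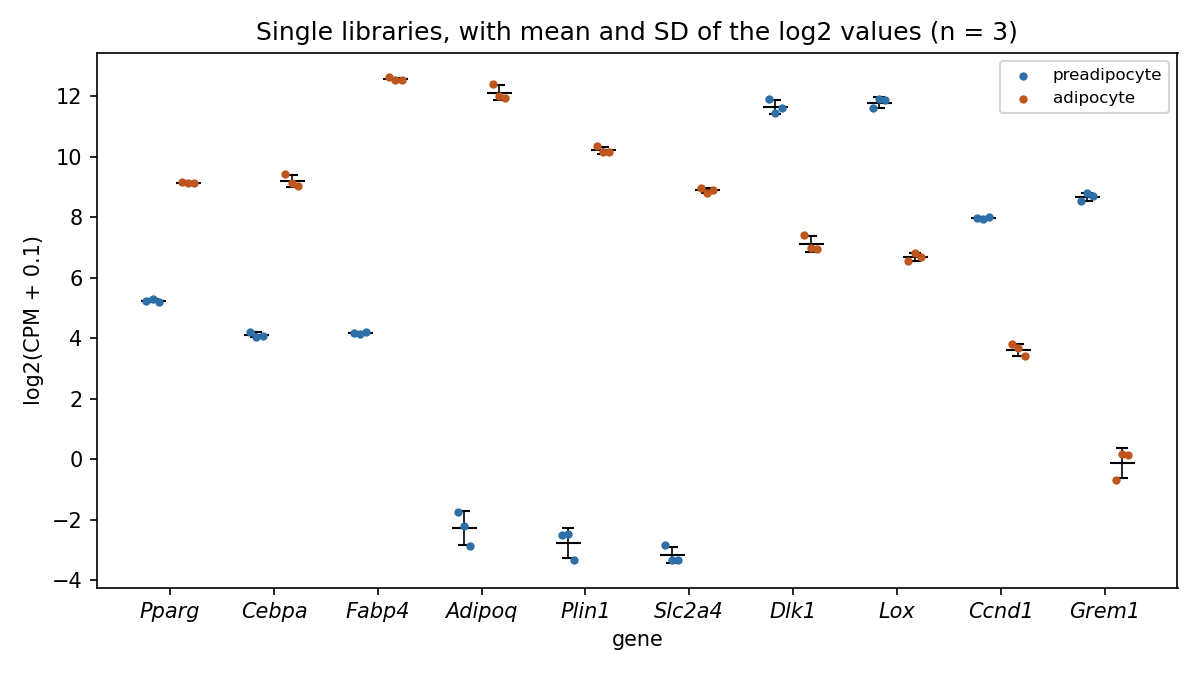
Abundance of 10 genes in single libraries as log2(CPM + 0.1), with 3 points per group and the mean and SD of the log2 values (n = 3). The groups do not overlap for any of the 10 genes.

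By the fixed rule, which ranks fitted log2 fold changes, the largest rises were of Cfd, Mrap, Cidec, Adipoq and Adig. The places of Mrap and Adig among them depend on the prior count. Cfd, which encodes the secreted protease adipsin, reached 3527 ± 876 CPM (SD, n = 3) from 2 preadipocyte counts, a ratio of 138702 (95% interval 38397 to 1145310). Mrap, an accessory protein of the melanocortin receptors, was at least 7054-fold higher, and Adig at least 4786-fold higher, since neither had a count in preadipocytes. Cidec, a lipid droplet fusion protein, rose from 6 to 209027 counts. The largest falls were of Grem1, Smoc2, Mmp9, Gpr176 and Ogn. Grem1, a secreted inhibitor of bone morphogenetic proteins, fell from 412.8 ± 36.5 to 0.847 ± 0.285 CPM (SD, n = 3), and the matrix proteoglycan gene Ogn fell from 685.0 ± 63.7 to 4.23 ± 0.67 CPM (SD, n = 3).

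Transcription factors of late fat cell formation rose in 9 of 10 tested members, and with total counts or limma on log2(TPM + 1) 8 rose, without Stat5b, and 1 fell. Klf15 rose from 2 to 12064 counts, a ratio of 6991 (95% interval 1935 to 57730), and the carbohydrate-responsive factor gene Mlxipl from 1 to 4688 counts, a ratio of 5434 (95% interval 975.2 to 214616). Ebf1 measured 121.6 ± 9.44 and 124.6 ± 10.95 CPM (SD, n = 3), and its call differed between settings. It was lower with total counts (-0.29) and with limma on log2(TPM + 1) (-0.43), and with the replicate block and a GC and length correction all 10 members were higher. The list passed camera (adjusted p = 7.44e-05) but not with an estimated correlation (adjusted p = 0.14). Early adipogenic factors went both ways, with 3 higher (Cebpb, Zfp423 and Nr4a1) and 7 lower of 11, and the list did not pass (camera adjusted p = 0.13, and 0.23 with an estimated correlation). It passed with fry (adjusted p = 1.25e-05) and with camera without the low-count filter. Nr3c1 was lower as well under 7 alternatives, the replicate block among them. Klf5 fell by 3.64 (SE 0.18) and Klf4 fell by 3.02 (SE 0.090) on the log2 scale, while Zfp423 rose by 1.77 (SE 0.097).

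Genes of fatty acid and triglyceride synthesis rose in 19 of 20 members, with a median log2 fold change of 4.89, or 4.88 with members at few counts set to their bounds. Thrsp, a regulator of lipid synthesis, rose from 0.141 ± 0.083 to 2162 ± 300 CPM and the glycerol phosphate enzyme gene Gpd1 from 0.611 ± 0.089 to 4996 ± 491 CPM (SD, n = 3). The exception was the elongase gene Elovl6, which fell by 2.57 on the log2 scale (SE 0.12). All 14 genes of fatty acid uptake and lipolysis rose, among them the fatty acid transporter Cd36 from 0.761 ± 0.287 to 2207 ± 240 CPM (SD, n = 3) and the beta-adrenergic receptor Adrb3 from 2 to 22761 counts, a ratio of 13190.5 (95% interval 3652 to 108918). With total counts or limma on log2(TPM + 1) 13 rose, where Slc27a1 (log2 fold change 0.44) lost its call (0.12 and -0.05). Both lists passed camera (adjusted p = 4.47e-10 and 4.62e-08) and passed with an estimated correlation (adjusted p = 0.030 for each), but not with the replicate block and an estimated correlation (adjusted p = 0.17 for each). Lipid droplet proteins rose in 8 of 10 tested members, whereas Plin3 fell by 0.90 on the log2 scale (SE 0.11) and 2 members fell with limma on log2(TPM + 1) or with the replicate block and a GC and length correction. The list passed camera (adjusted p = 0.00045) but not with an estimated correlation (adjusted p = 0.19).

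Insulin signalling and glucose uptake genes rose in 12 of 15 members. The 12 include Pdk1 (log2 fold change 2.22), which encodes a pyruvate dehydrogenase kinase and not a kinase of insulin signalling. The insulin-responsive glucose transporter gene Slc2a4 went from 1 to 32328 counts, a ratio of 37470 (95% interval 6725 to 1479970), and the hexokinase gene Hk2 rose by 4.12 (SE 0.088). Slc2a1, the widely expressed glucose transporter, fell by 0.97 on the log2 scale (SE 0.10), and with total counts or limma on log2(TPM + 1) 3 members fell in place of 1. With the replicate block and a GC and length correction 14 members rose and 1 fell. The list passed camera (adjusted p = 3.92e-05) but not with an estimated correlation (adjusted p = 0.14). Adipokine genes rose in 9 of 11 tested members (camera adjusted p = 0.00015, and adjusted p = 0.11 with an estimated correlation), while Angptl4 was not past the threshold at a log2 fold change of -0.04. With the replicate block, upper-quartile factors or without adipocyte replicate 1, 1 member fell. With total counts, limma on log2(TPM + 1) or the replicate block and a GC and length correction 2 fell, Angptl4 among them.

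All 19 tricarboxylic acid cycle genes, all 42 nuclear-encoded respiratory chain genes, all 18 genes of branched-chain amino acid breakdown and all 15 peroxisome genes rose (camera adjusted p = 4.47e-10, 1.86e-15, 4.80e-10 and 2.35e-07 in this order). With an estimated correlation the tricarboxylic acid cycle and respiratory chain lists did not pass (adjusted p = 0.068 and 0.14), and the branched-chain and peroxisome lists passed (adjusted p = 0.030 for each), but not with the replicate block as well (adjusted p = 0.17 for each). Pdhb, a subunit of pyruvate dehydrogenase, rose from 40.3 ± 0.72 to 961.4 ± 14.3 CPM and Uqcrfs1, a subunit of complex III, from 37.8 ± 1.31 to 570.9 ± 41.5 CPM (SD, n = 3). Bcat2, which starts branched-chain amino acid breakdown, rose by 5.75 on the log2 scale (SE 0.20), and the peroxisomal enzyme gene Ehhadh rose from 1 to 1236 counts, a ratio of 1433 (95% interval 257.1 to 56584). Fatty acid oxidation genes rose in 15 of 18 members (camera adjusted p = 4.65e-06, and adjusted p = 0.074 with an estimated correlation), with Acadvl up by 3.72 (SE 0.10), but Cpt1a and Pdk4 fell by 2.39 and 1.46 on the log2 scale.

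Mitochondrially encoded genes rose in 12 of 13 members (camera adjusted p = 3.14e-05, and adjusted p = 0.12 with an estimated correlation). The protein-coding ones took 3.19% ± 0.26 of counts in preadipocytes and 7.36% ± 0.23 in adipocytes (SD, n = 3). Their single values are uncertain, because 7 pseudogenes on chromosome 1 between 24611535 and 24616197 share 97.2% to 100% of their 31-mers with mitochondrial genes and took 1.49% ± 0.07 and 3.70% ± 0.17 of counts (SD, n = 3). The cytochrome oxidase gene mt-Co3, which has such a copy, did not pass (log2 fold change 2.97, SE 1.56, edgeR adjusted p = 0.11), but passed with the replicate block (5.06, also with a GC and length correction), limma on log2(TPM + 1) (6.51), limma-voom, no low-count filter and without preadipocyte replicate 3. The gene mt-Atp6, which also has a copy, rose from 403.1 ± 62.9 to 1676 ± 449 CPM (SD, n = 3). All 8 tested thermogenic genes rose (camera adjusted p = 0.00012, and adjusted p = 0.066 with an estimated correlation), among them the cytochrome oxidase subunit gene Cox8b, at least 2136-fold higher, but 7 of the 15 listed genes had too few counts to be tested. Ucp1, the uncoupling protein of brown fat, had 0 counts in preadipocytes and 1 in adipocytes.

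Glycolysis genes rose in 13 of 14 tested members (camera adjusted p = 2.76e-05, and adjusted p = 0.29 with an estimated correlation), with Aldoa up by 3.28 (SE 0.14), while the hexokinase gene Hk1 fell by 1.51 on the log2 scale. All 8 genes of the pentose phosphate pathway and cytosolic NADPH supply rose (camera adjusted p = 0.00018, and adjusted p = 0.11 with an estimated correlation), with Taldo1 up by 4.01 (SE 0.10). Cholesterol genes rose in 18 of 22 members with a median log2 fold change of 0.65 (camera adjusted p = 0.00041, and adjusted p = 0.066 with an estimated correlation). With limma on log2(TPM + 1) 9 rose and 4 fell, and with total counts 12 rose and 3 fell. In place of 1 member, 2 fell with upper-quartile factors, the replicate block, without adipocyte replicate 1 or without both libraries numbered 1. Pmvk, of the mevalonate pathway, rose by 2.16 (SE 0.14). Genes of the unfolded protein and integrated stress responses rose in 10 of 15 members (camera adjusted p = 0.012, and adjusted p = 0.14 with an estimated correlation). Trib3, induced in the integrated stress response, rose by 4.51 (SE 0.13), while the chaperone genes Hsp90b1 and Calr fell by 0.96 and 0.68 on the log2 scale, and 4 members fell with upper-quartile factors and 5 with total counts or limma on log2(TPM + 1). Circadian clock genes rose in 13 of 15 members (camera adjusted p = 0.00045, and adjusted p = 0.068 with an estimated correlation), with Nr1d1 up by 2.38 (SE 0.11). With the replicate block, without adipocyte replicate 1 or without both libraries numbered 1, 1 member fell, and with upper-quartile factors, total counts or limma on log2(TPM + 1) 2 fell. The number that rose was 11 with upper-quartile factors, total counts or without preadipocyte replicate 1 or 3, 9 with limma on log2(TPM + 1), and 12 with the effective length offset or without preadipocyte replicate 2 or adipocyte replicate 2 or 3.

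**Figure D3:**
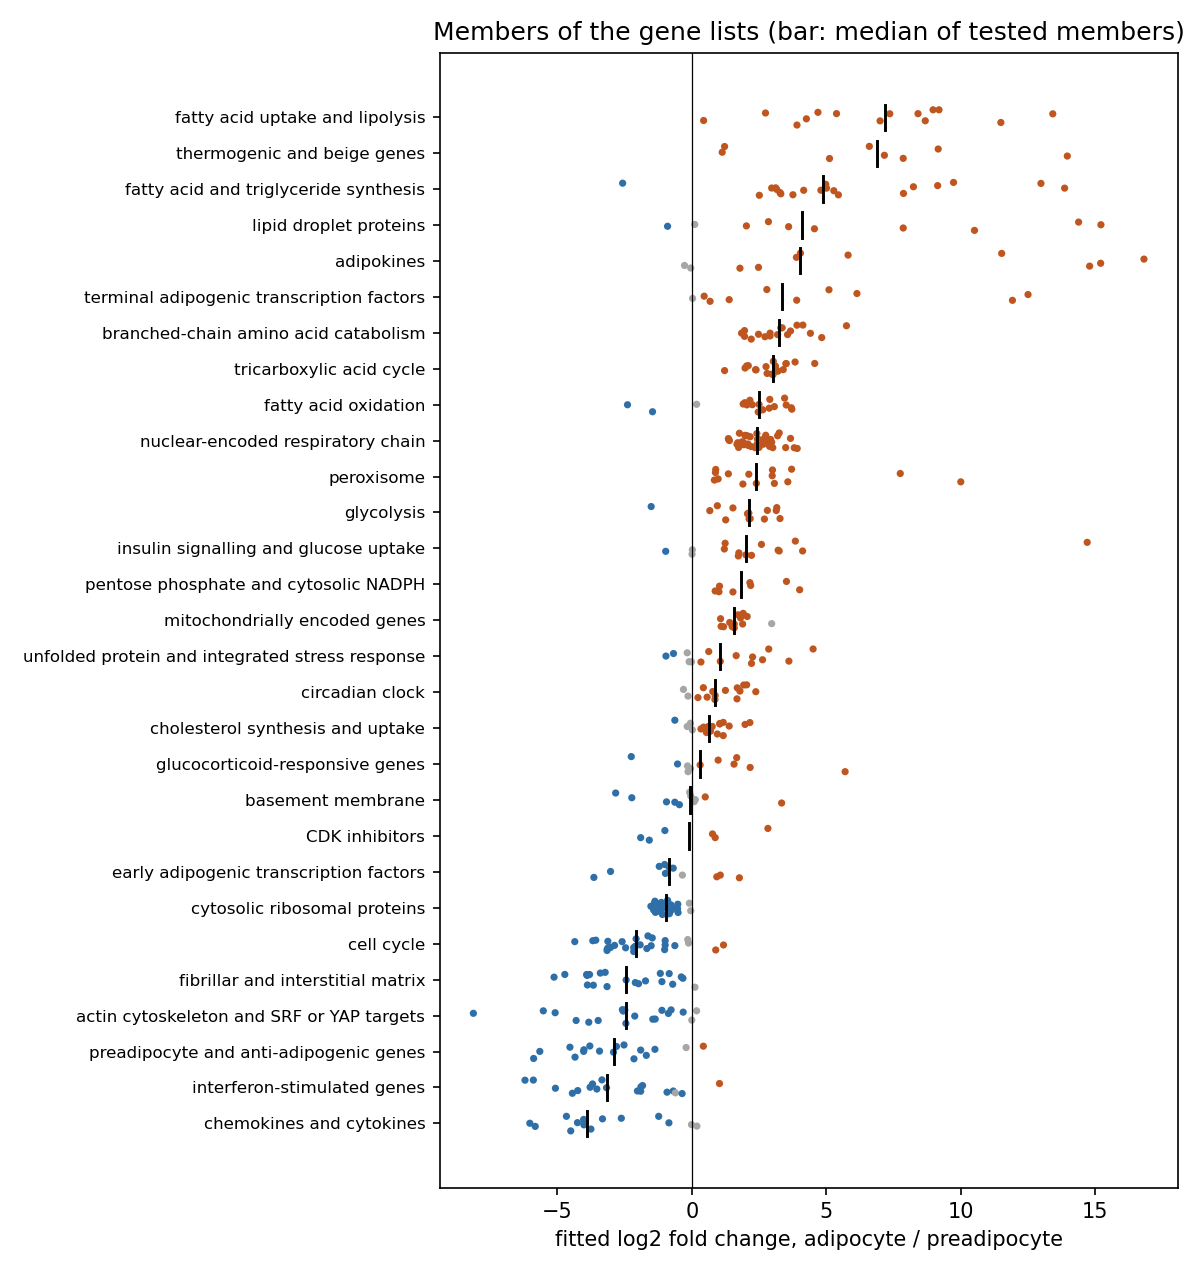
Fitted log2 fold change (adipocyte over preadipocyte) of each tested member of 29 gene lists, in orange where higher, blue where lower and grey where not past the threshold, with a bar at the median. Medians run from -3.88 for chemokines and cytokines to 7.18 for fatty acid uptake and lipolysis, and values of genes with few counts in a group depend on the prior count.

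Preadipocyte and anti-adipogenic genes fell in 15 of 17 tested members (camera adjusted p = 1.08e-05, and adjusted p = 0.066 with an estimated correlation). The transcription factor gene Gata2 fell from 16.003 ± 0.530 to 0.268 ± 0.120 CPM (SD, n = 3), and Wnt10a from 78 counts to 1, 67.3-fold lower (95% interval 12.1 to 2658). Tcf7l2 rose by 0.43 on the log2 scale (SE 0.10, edgeR adjusted p = 0.0042), a call lost with total counts (log2 fold change 0.10, adjusted p = 0.41) and limma on log2(TPM + 1) (0.02, adjusted p = 0.82), where adjusted p over all alternatives ran from 2.56e-07 to 0.82. Fibrillar matrix genes fell in 20 of 21 members and actin cytoskeleton genes in 17 of 19 tested members (camera adjusted p = 4.62e-08 and 4.65e-06, and adjusted p = 0.11 with an estimated correlation for each). Of the fibrillar list, 18 fell with the DESeq2 test or without preadipocyte replicate 1 or adipocyte replicate 3, and 18 to 21 over the alternatives that kept all members. With the replicate block and a GC and length correction 1 rose. Of the actin list, Wwtr1 measured 95.01 ± 6.76 and 107.7 ± 10.7 CPM (SD, n = 3). It passed upward under 6 alternatives, which were RLE factors, the DESeq2 test, the replicate block with and without a GC and length correction, and leaving out adipocyte replicate 1 or both libraries numbered 1. It passed downward with limma on log2(TPM + 1). The collagen cross-linking enzyme gene Lox fell from 3579 ± 410 to 102.9 ± 9.65 CPM, the matrix glycoprotein gene Tnc from 24.6 ± 0.17 to 0.926 ± 0.234 CPM and the myosin light chain gene Myl9 from 14.5 ± 2.38 to 0.312 ± 0.202 CPM (SD, n = 3). Ankrd1, a target of the YAP pathway, was at least 31.9-fold lower, with 111 preadipocyte counts and none in adipocytes. Basement membrane genes went both ways, with 2 higher and 5 lower of 11 (camera adjusted p = 0.38, and adjusted p = 0.75 with an estimated correlation), with 1 higher and 9 lower with total counts or limma on log2(TPM + 1), 5 higher and 5 lower with the replicate block and a GC and length correction, and 1 higher and 5 lower without the 50 most abundant genes. Lama2 fell by 2.83 (SE 0.21).

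Cell cycle genes fell in 24 of 28 members (camera adjusted p = 1.32e-06), and the list passed with an estimated correlation (adjusted p = 0.030) but not with the replicate block as well (adjusted p = 0.17). Ccnd1, the cyclin of G1 phase, fell from 251.8 ± 6.76 to 12.3 ± 1.70 CPM and the proliferation marker Mki67 from 29.2 ± 2.67 to 2.26 ± 0.42 CPM (SD, n = 3). The cyclin E genes went the other way, and Ccne1 rose by 1.18 on the log2 scale (SE 0.10). Ccne2 rose by 0.89, a call lost with total counts or limma on log2(TPM + 1). CDK inhibitors split into 3 higher and 3 lower of 6 tested (camera adjusted p = 0.93, and adjusted p = 0.94 with an estimated correlation), with Cdkn2c up by 2.83 (SE 0.081).

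Chemokine and cytokine genes fell in 12 of 14 tested members (camera adjusted p = 0.00015, and adjusted p = 0.11 with an estimated correlation), with Ccl2 down from 36.8 ± 4.23 to 0.564 ± 0.089 CPM (SD, n = 3). With the replicate block, without adipocyte replicate 3 or without both libraries numbered 1, 1 member rose. Interferon-stimulated genes fell in 17 of 19 members (camera adjusted p = 0.00010, and adjusted p = 0.32 with an estimated correlation), with Oasl2 down from 55.8 ± 17.1 to 0.753 ± 0.221 CPM (SD, n = 3), and 1 member rose. Cytosolic ribosomal protein genes fell in 26 of 28 members, with a median log2 fold change of -0.97 (camera adjusted p = 3.37e-06, and adjusted p = 0.33 with an estimated correlation), with Rps4x down from 1078 ± 106 to 376.0 ± 29.0 CPM (SD, n = 3), and 24 to 28 fell over the alternatives that kept all members. Many of these genes have processed pseudogenes that can share their reads, so their counts are uncertain. Glucocorticoid-responsive genes showed 6 higher and 2 lower of 11 tested (camera adjusted p = 0.19, and adjusted p = 0.57 with an estimated correlation), with 4 lower with the replicate block, upper-quartile factors, without adipocyte replicate 1 or without both libraries numbered 1, and 5 lower with total counts or limma on log2(TPM + 1). Glul, encoding glutamine synthetase, rose by 5.70 (SE 0.090).

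Most markers of other cell types had too few counts to be tested, but some were well above the floor. No epithelial marker was tested, and the most abundant, Krt18, had 9 preadipocyte and 51 adipocyte counts. Of the endothelial markers 1 of 9 was tested, Pecam1, at 0.515 ± 0.207 and 0.381 ± 0.198 CPM (SD, n = 3). Of the 9 muscle markers only Des was tested and rose by 5.45 (SE 0.16), from 1.51 ± 0.29 to 66.0 ± 8.27 CPM (SD, n = 3). Macrophage markers had 2 of 3 tested members lower (camera adjusted p = 0.56, and adjusted p = 0.75 with an estimated correlation). Their most abundant member, Cd14, measured 3.75 ± 0.72 and 2.04 ± 0.79 CPM (SD, n = 3). Its edgeR adjusted p of 0.022 (log2 fold change -0.88) became 0.072 without preadipocyte replicate 1, within a range of 0.000103 to 0.0722 over all alternatives. Osteoblast markers showed 2 higher and 4 lower of 6 tested (camera adjusted p = 0.13, and adjusted p = 0.23 with an estimated correlation). Spp1, the most abundant, fell by 5.65 (SE 0.088), from 227.4 ± 10.5 to 4.54 ± 0.041 CPM (SD, n = 3). With a minimum of 1 CPM in 3 libraries, no osteoblast marker rose. Chondrocyte markers had 1 of 3 tested members higher, Col11a2 (camera adjusted p = 0.34, and adjusted p = 0.53 with an estimated correlation). Col11a2 rose from 14.1 ± 3.09 to 58.2 ± 7.70 CPM (SD, n = 3). Neuronal markers had 1 higher and 1 lower of 3 tested (camera adjusted p = 0.77, and adjusted p = 0.79 with an estimated correlation). Snap25 was at least 99.3-fold higher and Map2 fell by 5.34 (SE 0.24). The replicate block with or without a GC and length correction, no low-count filter, and leaving out preadipocyte replicate 1, adipocyte replicate 3 or both libraries numbered 1 gave 2 higher neuronal markers in place of 1.

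In total 25 of 33 tested lists passed camera with the preset correlation, 18 upward and 7 downward. With an estimated correlation 5 passed, and with the replicate block and an estimated correlation 0 passed. An estimated correlation limits camera to the residual degrees of freedom, which are few here and fewer with the block. Most lists had the same adjusted p of 0.17 there, so this setting cannot tell lists that hold from lists that do not. With the preset correlation the block changed 0 list calls. Camera with the preset correlation also passed up to 26 lists when the 6 libraries were regrouped, so the number of lists alone does not set the real grouping apart. Each regrouping holds unequal numbers of both states in a group, so part of the real difference remains. The regroupings therefore cannot tell how many lists would pass without a difference.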

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

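Leaving out both libraries numbered 1, leaving out ribosomal RNA, 7SL, 7SK and mitochondrial gene copies, the block with a GC and length correction, and the block with an estimated list correlation were chosen after the data were seen. The numbers of genes stayed within 1.5 times their reported values under the other alternatives run, but limma on log2(TPM + 1) gave 3266 higher genes and 1576 at least 2-fold higher genes, and the cause was not tested. With this setting 219 calls turned direction, and with the effective length offset 1. Leaving out 1 library at a time gave 4929 to 5466 higher, 5120 to 5606 lower, 2909 to 3042 at least 2-fold higher and 3239 to 3306 at least 2-fold lower genes, and 25 lists each time. Both libraries numbered 1 left out gave 5665 higher and 5843 lower genes, and the RNAs and copies left out 5252 and 5574. The replicate block gave 5763 higher and 6212 lower genes and 25 lists. It moved 1 or 2 members of several lists past the threshold, named or not, and changed no call of a list or of a gene taken by the naming rule. Over the 19 alternatives that left out neither the 50 most abundant nor the mitochondrially encoded genes, the preadipocyte list had 13 to 16 lower members, chemokines 10 to 13, interferon-stimulated genes 15 to 18, the actin list 16 to 19 and macrophage markers 1 to 3. Higher members were 18 or 19 for fatty acid and triglyceride synthesis, 12 or 13 for glycolysis, 8 to 10 for the unfolded protein list, 5 or 6 for glucocorticoid-responsive genes and 2 or 3 for CDK inhibitors. Up to 1 thermogenic gene fell. Camera with an estimated correlation gave 5 lists, and the replicate block with an estimated correlation 0 lists. Fry, run only without the block, passed 29. Fry asks whether the genes of a list changed, not whether they changed more than other genes. Its number of lists is therefore not comparable with those of camera. Of 63 genes taken by the naming rule with a fold change, 61 kept their direction and side of the threshold under every alternative that kept them, and Tcf7l2 and Cd14 did not. Most of the 63 were taken for large changes in these same data, so their stability does not stand for that of other genes. Of all 10827 calls, 1338 were lost with total counts and 1793 with limma on log2(TPM + 1).

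For the number of genes, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 5252 higher, 5575 lower, 2849 at least 2-fold higher and 3211 at least 2-fold lower genes, and 1 of the 10 splits, the real one, gave as many in each case. The highest of the other 9 was 0 by edgeR, with 170 genes at an unadjusted p under 0.05. Each of those splits mixes both states in each group, which widens the spread within groups. The mixing is unequal, so part of the difference between the states remains in each split and can make the same lists pass camera. For the lists, 5 of the 10 splits, the real one included, gave at least the real 25, and the highest other gave 26. The 4 splits that part all 3 pairs, the real one included, gave 25 or 26 lists. The other splits part 1 pair. In simulated data recovery was incomplete at 1.5-fold, so small changes may be missed at this number of libraries. Far fewer genes changed there than in the real data, which makes the adjusted threshold stricter. The simulated recovery therefore does not give the share missed here.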

Other observations

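The tests of the histone genes and of extra copies at the Mdm2 locus were chosen after the result was seen, and the test of shared sequence at the Mdm2 locus was added after the first test of that pattern. The genes named in this paragraph were chosen after their values were seen. The lactate receptor gene Hcar1 was at least 3313-fold higher in adipocytes, at 126.8 ± 1.63 CPM (SD, n = 3), and the fatty acid receptor genes Ffar2 and Ffar4 were at least 1695-fold and 979.4-fold higher. The thyrotropin receptor gene Tshr was at least 1254-fold higher. None of these 4 genes had a count in preadipocytes. The complement gene C3 rose from 1637 ± 44.2 to 4979 ± 317 CPM (SD, n = 3; edgeR adjusted p = 1.42e-07). Among the genes that fell, the secreted growth factor gene Ptn went from 6211 ± 178 to 222.5 ± 22.6 CPM, the plasminogen activator gene Plat from 236.3 ± 12.2 to 2.22 ± 0.14 CPM, the matrix protease gene Mmp3 from 30.2 ± 0.76 to 0.395 ± 0.146 CPM and the prolactin family gene Prl2c2 from 138.8 ± 3.99 to 1.87 ± 0.34 CPM (SD, n = 3). Prl2c2 has close relatives that can share its reads, so its count is uncertain.

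Summed transcripts of the nuclear-encoded respiratory chain list rose 6.03-fold, and those of the mitochondrially encoded genes with their chromosome 1 copies 2.96-fold. The ratio of the first sum to the second was 0.0863 ± 0.0132 in preadipocytes and 0.175 ± 0.023 in adipocytes (SD, n = 3; 2-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

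The 2 libraries numbered 1 deviated from their groups in the same direction, with a correlation across genes of 0.66. In both, the deviation followed GC content (rho 0.60 and 0.66 across genes) and Malat1 was lower than in the other libraries of the group, by -0.89 and -1.41 on the log2 scale. After the trends with GC content and length were removed the correlation was 0.45, above the bound set beforehand. The trends took out 36.1% of the variance of the deviations in preadipocyte library 1 and 41.1% in adipocyte library 1. These trends may thus account for part of the deviation but not for all of it. A GC or length bias that averages per gene do not capture could not be excluded. Shared reads are argued against, since the correlation was 0.71 among 7606 genes with whole expected counts (within 0.005). A shared day or culture was not tested and stays open, and no biological explanation was tested.

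Histone genes went against the cell cycle list. Of 70 histone genes 24 had enough counts to be tested, and 22 of these were higher and 1 lower in adipocytes (2 lower with limma on log2(TPM + 1)). The sum over all 70 was 85.5 ± 4.14 against 444.2 ± 34.2 CPM (SD, n = 3, 2-sided exact permutation p = 0.1, the smallest possible). A few genes carried much of it, with adipocyte means of 169.3 CPM for Hist1h1c, 77.0 for Hist1h2bc and 57.6 for Hist2h2aa2. The cell cycle list, fixed beforehand, had a median log2 fold change of -2.08, the opposite of what more dividing cells would give, but this fall is part of the observation and no separate test of it. Carry-over of RNA without poly(A) tails could not be excluded, since 7SL and 7SK RNA were 4.19 times the preadipocyte mean in adipocyte libraries 1 and 3, against 5.15-fold for the histone sum, while 7SK alone was 2.18-fold and ribosomal RNA 1.54-fold there. Against it, 7SL and 7SK differed 36.2-fold among the adipocyte libraries and the histone sum 1.17-fold, but that rests on adipocyte library 2. A change of histone transcripts with differentiation, such as a gain of poly(A) tails, may be involved and was not tested.

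Mdm2 (chromosome 10, 117688875 to 117710758, GRCm38) and its neighbour Slc35e3 (117733679 to 117746365) were among the most abundant transcripts in all 6 libraries, at 2723 to 3596 and 1331 to 2428 CPM, while the flanking genes Cpm and Nup107 averaged 4.78 and 18.6 CPM. Shared reads were tested as an explanation, and 83.3% of the 2 genes' expected counts were not whole, which met the bound set beforehand. That test is weak, because a fraction of 1 read meets it and 37.4% of the counts of all tested genes were not whole. Of the 31-mers of their transcripts, 2.0% in Mdm2 and 21.6% in Slc35e3 occur in other genes, for Slc35e3 only in Gm7902 and Gm7341. The low share argues against sharing for Mdm2, though the positions of the reads were not examined. For Slc35e3 sharing stays open. Of 17 other tested p53 targets, fixed before this test, 0 (0%) lay in the top 5% of genes, and their median percentile was 65.7. A very high abundance shared by p53 targets was thus not seen. Abundance without a comparison of p53 states does not measure p53 activity, so that explanation stays open. Extra copies of the locus cannot be told apart from local regulation, because a run of 2 adjacent genes was raised and DNA was not measured.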
